A study of Mus musculus with 30 samples.

How the data were processed

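ChIP-seq libraries from the mouse pancreatic tumour cell lines 6419c5 and 6694c2 were compared between wild-type cells and cells in which Kdm3a had been knocked out. The series holds 30 samples. Libraries with values for H3K9ac (8), H3K9me2 (8) and KDM3A (10) were used, and the 4 input samples were not used here, so enrichment over input was not analysed here. Each line and genotype had 2 libraries per antibody, except for KDM3A in 6419c5, which had 3. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures or whether each knockout was a single clone, so the p-values measure only the spread between these samples, which may be technical.

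The authors aligned and processed the reads with Bowtie2, SAMtools, MACS2 and bedtools on the mm10 build, per the submitters' processing notes, which give no version, role or order of the tools. The deposited tables hold 1 list of regions per antibody, shared by all of its libraries, with 1 value per region and library. The tables are labelled as TPM, but every deposited column summed to 1000000 over the regions of its table and moved in equal steps whatever the region length, so they are counts per 1000000 reads in the listed regions, or CPM. The planned limma test on log2 values was kept with CPM in place of TPM. Dividing by the step of a column gave whole reads (within 0.05 of a whole number) for 100% of values in the H3K9ac and KDM3A libraries and for all but single values in the H3K9me2 libraries. In 2 H3K9me2 libraries the step lay below the smallest value of the column, and count tests were therefore run for H3K9ac and KDM3A only. The H3K9me2 column names carry the word combine, so a column may join several sequencing runs. How the regions were called, from single or pooled libraries, is not given in the sources used here. Because CPM are relative within a library, a change of all regions together cannot be seen.

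Depth was taken as the reads in the listed regions. It was 4.70 to 11.8 M reads for H3K9ac (median 34 to 83 reads per region), 18.0 to 24.5 M reads for H3K9me2 (median 82 to 108 reads) and 0.879 to 2.11 M reads for KDM3A (median 3 to 9 reads). The chi-square per degree of freedom between the read counts of 2 libraries of a group was 1.13 to 2.55 for H3K9ac, 1.43 to 3.00 for H3K9me2 and 1.39 to 2.26 for KDM3A, and the highest values of the histone marks were those of the 6694c2 knockout replicates.

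For each antibody, limma (version 3.58.1, R 4.3.3) was fitted to log2(CPM + 1) with a mean for each of the 4 groups of line and genotype and empirical Bayes moderation with a trend. Regions with a mean of at least 1 CPM were tested, two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Of the 35013 H3K9ac, 92847 H3K9me2 and 221550 KDM3A regions, 34937, 86177 and 221548 were tested. The contrasts were knockout against wild type as the mean of both lines, the same within each line, the difference of the knockout effect between the lines, and 6419c5 against 6694c2 in wild type. Fold changes are on the log2(CPM + 1) scale, which understates the change of low regions. The procedure was tested on simulated reads with the means and depths of these libraries. In each simulation up to 100 regions changed 2-fold and 100 changed 4-fold, up or down, and all others stayed the same. It recovered 79% of 2-fold and 99% of 4-fold changes for H3K9ac, 93.9% and 100% for H3K9me2, and 0% and 12% for KDM3A, with 4, 9 and 0 false calls. All groups of an antibody were given the same spread, and no chromosome was shifted. The wider spread of the 6694c2 knockout replicates was therefore not simulated, and these figures hold only for that setting.

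Regions were named by overlap with, or distance of up to 100 kb from, protein-coding genes of the GRCm38.p6 annotation, the assembly that mm10 corresponds to. Of the regions, 66.4% for H3K9ac, 39.4% for H3K9me2 and 43.8% for KDM3A overlapped a gene. A gene's value was log2 of the summed CPM of all regions overlapping the gene body or 5 kb either side, plus 1. Either side was used in place of the planned upstream side because the annotation used here carries no strand. For the same reason the intended values from 2 kb around transcription starts were replaced by values from 2 kb around either gene end. A region can count towards several neighbouring genes, so members of gene clusters share values.

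The lists of genes, the contrasts, the naming rule and the main alternatives were fixed before the data were examined. The 16 lists covered EGF receptor signalling, KLF and TGF-beta/SMAD factors, chemokines and cytokines, antigen presentation and interferon response, hypoxia and glycolysis, epithelial and pancreatic ductal identity, mesenchymal transition, H3K9 methylation enzymes and readers, AP-1 and immediate early factors, the cell cycle, genes reported as Kdm3a targets in other tissues, ribosomal and housekeeping genes, and markers of fibroblasts and stellate cells, leukocytes, endothelium, and acinar and islet cells. To these came 5 families chosen by symbol (olfactory receptor, protocadherin cluster, Hox, Zfp and vomeronasal receptor genes). Of 341 list entries 340 matched the annotation, all but Cxcl11. Lists with at least 3 measured genes were tested with camera, with a preset and with an estimated correlation, and with fry, for the mean of both lines. Members past the threshold were counted after adjustment over all genes and over the list alone.

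Kdm3a, Egfr, Klf5 and Smad4 were always named. The named regions were up to 10 higher and 10 lower regions per antibody with the largest absolute log2 fold change among those past the threshold with the same sign in both lines, a mean above the median region, and at most 1 region per gene. Up to 3 each way were named for the within-line and difference contrasts. Where fewer than 3 passed, the 5 regions of smallest p were given as values. From each list up to 4 genes past the threshold adjusted over the list alone were named, largest change first, and otherwise up to 2 as values. Some genes that this rule would name are not reported here.

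Alternatives planned beforehand were other pseudocounts and filters, quantile normalization, median scaling, centring every library on the median of each chromosome, a replicate block, a fit on each line alone, and leaving out each library in turn. Added after seeing the data were edgeR (version 4.0.16, quasi-likelihood) on the recovered reads, a correction of each group for the local level of KDM3A reads in windows of 5 Mb, the gene-end values, list tests under the other scalings and within lines, runs of neighbouring H3K9me2 regions called the same way, centring at KDM3A regions, and centring in 5 Mb windows with at least 10 regions, applied to the agreement of the lines and to H3K9ac against H3K9me2 over genes. Centring on a chromosome removes its median only, so that a shift of part of a chromosome remains. The level of KDM3A reads around a named region was taken over 1 Mb centred on it. One KDM3A library, 6419c5 wild-type replicate 3, was left out of edgeR because its step lies close to 1 CPM. Correlations over regions or genes carry no replicate-based p, since regions and genes are not independent replicates. The signal at regions with lower KDM3A was compared by exact permutation of the genotypes within lines.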

Results

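H3K9ac, H3K9me2 and KDM3A were profiled by ChIP-seq in 6419c5 and 6694c2, mouse pancreatic tumour cell lines of the C57/BL6 strain grown in culture without treatment, each as wild type and with Kdm3a knocked out. Kdm3a encodes a demethylase that removes methyl groups from lysine 9 of histone H3. H3K9ac marks active promoters and enhancers, and H3K9me2 is spread over silent chromatin. The data comprised 8 H3K9ac libraries, 8 H3K9me2 libraries and 10 KDM3A libraries, with 2 per line and genotype, or 3 for KDM3A in 6419c5. Replicate libraries of 1 group correlated over regions (log2 values) at r of 0.986 to 0.992 for H3K9ac and 0.982 to 0.991 for H3K9me2, and at 0.139 to 0.263 for KDM3A. Libraries of different lines correlated at 0.90 to 0.935, 0.92 to 0.943 and 0.0126 to 0.204. Depth in the listed regions was 4.70 to 11.8 M reads per library for H3K9ac, 18.0 to 24.5 M for H3K9me2 and 0.879 to 2.11 M for KDM3A, a median of 34 to 83, 82 to 108 and 3 to 9 reads per region. Whether replicates were separate cultures, or each knockout a single clone, is not stated in the labels, so p-values here measure the spread between these libraries. The H3K9ac regions covered 35.4 Mb, the H3K9me2 regions 388 Mb and the KDM3A regions 55.7 Mb.

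Kdm3a itself (chromosome 6, 71588970 to 71632990) kept its H3K9ac level in 6419c5 knockout cells, with 77.6 and 81.2 CPM in the wild-type libraries and 81.0 and 81.5 CPM in the knockout libraries. In 6694c2 its H3K9ac fell from 121 and 120 CPM to 99.4 and 85.8 CPM (log2 fold change -0.38 ± 0.06 SE, n = 2 per group, limma adjusted p = 0.000189), and the lines differed in this effect (adjusted p = 0.00187). H3K9me2 over Kdm3a lay between 7.59 and 8.74 CPM in the 6419c5 libraries and between 9.81 and 11.1 CPM in the 6694c2 libraries, a difference between genotypes of 0.04 on the log2 scale (adjusted p = 0.782). KDM3A signal over Kdm3a was 114, 117 and 110 CPM in wild-type and 105, 115 and 104 CPM in knockout 6419c5 libraries, and 144 and 154 CPM against 173 and 147 CPM in 6694c2 (mean log2 difference 0.01, adjusted p = 0.994). ChIP signal over the gene does not measure its transcript or protein, so these values do not check the knockout.

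Egfr, which encodes the epidermal growth factor receptor (chromosome 11, 16752203 to 16913907), lost H3K9ac in the 6694c2 knockout, by more than 1 log2 unit on average. Its level fell from 59.0 and 50.3 CPM to 16.0 and 33.9 CPM (-1.19 ± 0.20 SE, adjusted p = 0.000199), while in 6419c5 it was 129 and 125 CPM in wild type and 138 and 139 CPM in the knockout (0.12, adjusted p = 0.716). The lines differed in this effect (adjusted p = 0.00181). The knockout libraries of 6694c2 lay far apart (16.0 and 33.9 CPM), so the size of the loss is uncertain. The SE is moderated by the spread of other genes and need not show that gap. Klf5, a zinc-finger transcription factor, lost H3K9ac in the 6694c2 knockout, from 267 and 292 CPM to 196 and 191 CPM (-0.52 ± 0.05 SE, adjusted p = 2.54e-06), and was unaltered within error in 6419c5 (0.01, adjusted p = 0.923). Klf5 lies on chromosome 14, where the median H3K9ac region was lower by -0.378 in that knockout, and with every chromosome centred the change was -0.09 (adjusted p = 0.251). Smad4, the common mediator of TGF-beta signalling, rose in the 6419c5 knockout from 124 and 117 CPM to 144 and 149 CPM (0.28, adjusted p = 0.00121). It lies on chromosome 18, where the median H3K9ac region was higher by 0.209, and the centred change was 0.04 (adjusted p = 0.651). H3K9me2 over Egfr and Klf5 was lower in the 6694c2 knockout by log2 values of -0.19 (adjusted p = 0.0145) and -0.42 (adjusted p = 0.0128), neither of which passed with chromosomes centred (adjusted p = 0.0771 and 0.795). Over the mean of both lines H3K9me2 did not pass at Egfr (-0.10, adjusted p = 0.0699), Klf5 (-0.21, adjusted p = 0.0775) or Smad4 (0.10, adjusted p = 0.366), and KDM3A did not at Egfr (-0.06, adjusted p = 0.96) or Smad4 (0.04, adjusted p = 0.971). No KDM3A region was assigned to Klf5.

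**Figure D1:**
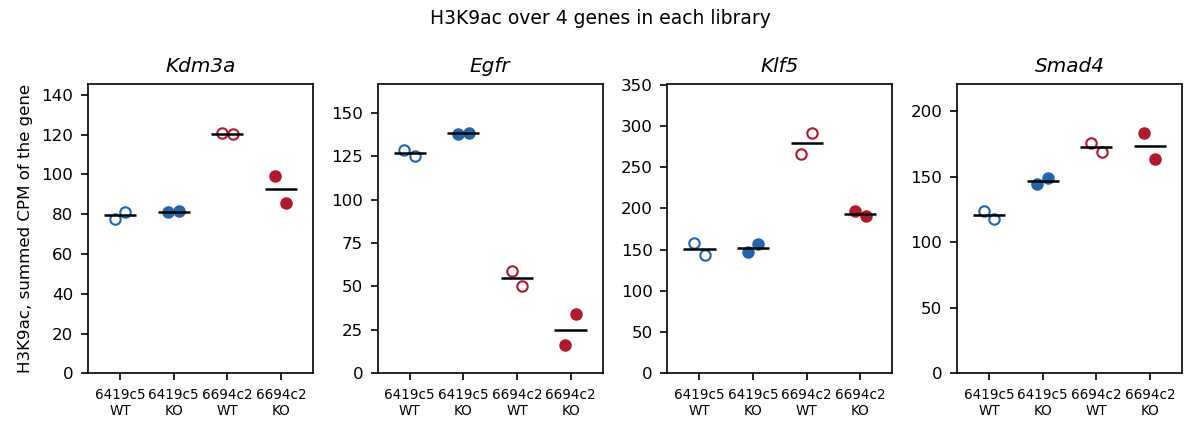
H3K9ac CPM over Kdm3a, Egfr, Klf5 and Smad4 in each library (points) and the mean of each group (bars), by line and genotype. Egfr fell from 59.0 and 50.3 CPM to 16.0 and 33.9 CPM in the 6694c2 knockout and did not pass the test in 6419c5, where it was 125 to 139 CPM.

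H3K9ac differed between knockout and wild type at 5644 regions as the mean of both lines, of which 2127 also passed with chromosomes centred. Tested in each line, 292 regions were higher in both, 296 lower in both and 534 changed in opposite directions. The largest changes shared by both lines were losses. Acetylation fell furthest at a region in Cdyl2 (chromosome 8, 116732093 to 116733312), which encodes a chromodomain protein, from 19.9 to 3.91 CPM in 6419c5 and from 33.1 to 1.70 CPM in 6694c2 (mean log2 fold change -2.91 ± 0.16 SE, limma adjusted p = 4.63e-11, lower in 4 of 4 knockout libraries than in wild type of their line). It fell also at Mycn (chromosome 12, 12940770 to 12941850), a proto-oncogenic transcription factor, by -1.58 in 6419c5 and -3.19 in 6694c2, and beside Dio3, which inactivates thyroid hormone, by -1.50 and -2.90. The largest gain over a gene was in Nav2 (chromosome 7, 49246188 to 49248837), from 30.5 to 67.5 CPM in 6419c5 and from 21.0 to 51.5 CPM in 6694c2 (1.19 ± 0.06 SE, adjusted p = 3.23e-11).

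Of 34937 H3K9ac regions 5644 passed for the mean of both lines, 2503 higher and 3141 lower in the knockout, and 155 of them changed at least 2-fold (10 higher, 145 lower). The other named losses were Nectin1, a cell adhesion molecule, Sall1, Rims2, Rin3, Ppfibp2, Lyplal1 and Sulf2 (-2.52 to -1.88), and the other named gains were Slc43a3, Arhgef10l, Rasgrp3, Pcdh7, Map6, Ypel5, Txndc2, Prrx1 and a region of chromosome 12 with no gene nearby (0.84 to 1.19). The regions at Nectin1, Sall1, Rims2, Rin3, Sulf2 and Arhgef10l moved in 6694c2 and did not pass in 6419c5 (-0.75, -0.20, -0.45, -0.08, -0.08 and 0.01). With every chromosome centred 2563 regions passed, of which 2127 were among the 5644, and all 20 named regions passed. edgeR on the recovered reads called 5565. Leaving out any single 6419c5 library lowered the count to 3602 and 3538 without the wild-type replicates 1 and 2 and to 3673 and 3632 without the knockout replicates.

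Chromosomes, or long parts of them, shifted between knockout and wild type in all 3 antibodies. In 6419c5 the median region of chromosome 1 was lower in the knockout by log2 values of -0.302 for H3K9ac, -0.301 for H3K9me2 and -0.436 for KDM3A, and that of chromosome 18 was higher by 0.209, 0.203 and 0.145. In 6694c2 chromosome 14 was lower by -0.378, -0.397 and -0.665, chromosome 13 by -0.225, -0.348 and -0.481, and chromosome 4 was higher by 0.326, 0.380 and 0.425. Over the 20 chromosomes, the shifts of H3K9ac and H3K9me2 followed those of KDM3A reads with r of 0.966 and 0.954 in 6419c5 (rho 0.905 and 0.892) and 0.877 and 0.941 in 6694c2 (rho 0.904 and 0.922). The permutation p over chromosomes was 1e-04 in each case, the smallest that could be given, and these were 4 correlations over chromosomes of the same cells. Some shifts changed within a chromosome. A split of each chromosome at the place that best parted its KDM3A reads in 5 Mb windows, chosen after the data were seen, gave a step of at least 0.3 on 3 chromosomes, all in 6419c5: chromosome 7 at 70 Mb (median log2 difference 0.253 before and -0.28 after), chromosome 17 at 35 Mb (0.0946 and 0.491) and chromosome 5 at 135 Mb (0.033 and 0.358). H3K9ac windows had medians of 0.101 and -0.172, -0.0108 and 0.278, and -0.021 and 0.222 on either side of these splits, and H3K9me2 windows 0.0369 and -0.228, -0.00621 and 0.345, and -0.044 and 0.141. Centring on the median of a chromosome does not remove such steps.

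**Figure D2:**
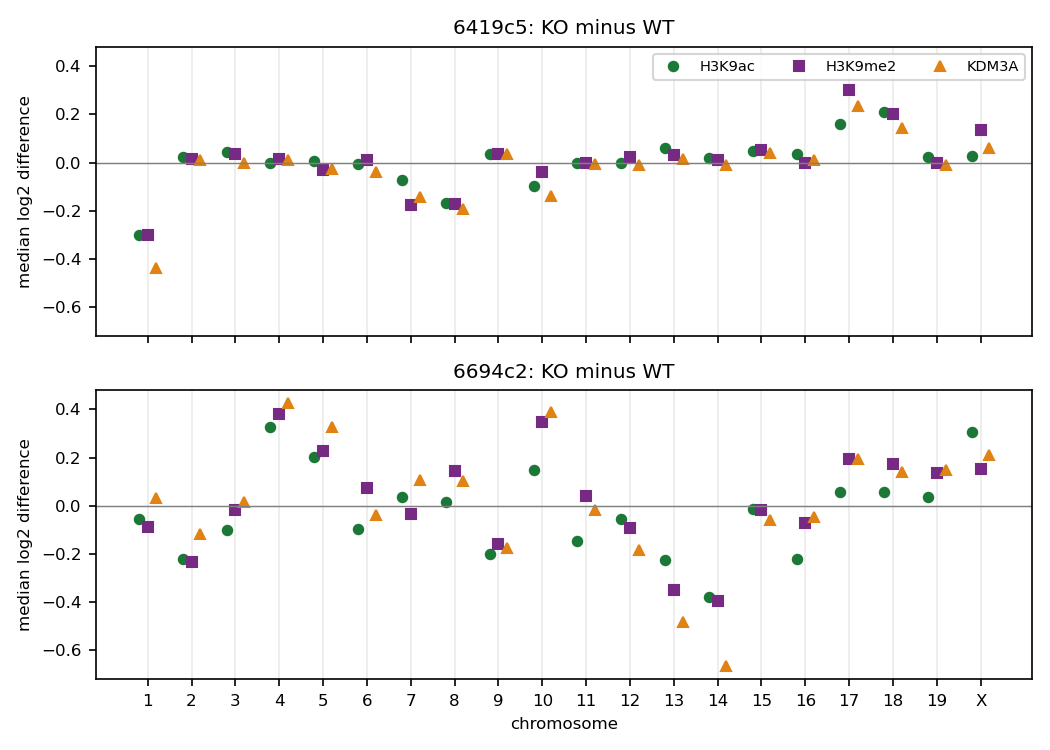
Median log2 difference between knockout and wild type per chromosome, H3K9ac and H3K9me2 against KDM3A reads, 1 panel per line. Chromosome 14 of 6694c2 lay at -0.378 for H3K9ac and -0.665 for KDM3A, and r over the 20 chromosomes was 0.877 to 0.966.

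Per gene, 5609 of 13049 passed for H3K9ac over both lines (2392 higher, 3217 lower), and 2366 with chromosomes centred. Counts adjusted over the list alone equalled those over all genes except where both are given. Of 24 epithelial and pancreatic ductal genes, 4 rose and 11 fell as the mean of both lines, but the lines differed, with 3 higher and 12 lower in 6419c5 and 7 higher and 3 lower in 6694c2. Those that fell included Foxa1, a pioneer transcription factor (-0.82, adjusted p = 2.86e-06), the tight-junction gene Cldn7 (-0.67), the epithelial ETS factor Elf3 (-0.50) and the chloride channel gene Cftr (-0.50). Of 16 mesenchymal transition genes, 6 rose and 2 fell. Prrx1 rose by 0.76 (-0.0199 with gene-end values). The mean of Twist1, 0.58, joined a gain of 1.80 in 6419c5 and a loss of -0.63 in 6694c2, while Snai2 and the fibronectin gene Fn1 changed by -0.65 and -0.61. Of 24 antigen presentation and interferon genes, none rose and 6 fell, led by the adjacent immunoproteasome and peptide transporter genes Psmb9 and Tap1, which share their regions (-0.95, adjusted p = 0.000123), with Irf9 at -0.50 and Isg15 at -0.23. Of 18 chemokine and cytokine genes, 2 rose and 6 fell: Il18 (-0.44), Cxcl16 (-0.29) and Cx3cl1 (-0.28) were lower and Cxcl3 (0.40) was higher. The chromosome-centred p of Il18, Cxcl3 and Irf9 was 0.173, 0.093 and 0.17. With chromosomes centred 3 epithelial genes rose and 8 fell, 7 mesenchymal genes rose and 2 fell, 1 antigen presentation gene rose and 5 fell, and 3 chemokine and cytokine genes fell.

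Of 24 EGF receptor signalling genes, 7 rose and 3 fell (3 and 2 with chromosomes centred). Beside Egfr (-0.53 as the mean of both lines), the feedback inhibitor Spry2 changed by -0.26, the ligand gene Hbegf by 0.20 and the receptor gene Erbb2 by -0.19, and with chromosomes centred Spry2 and Hbegf no longer passed (-0.04 and 0.03). Of 27 KLF and TGF-beta/SMAD genes, 9 rose and 4 fell (8 and 2 centred), including Klf4 (0.34, from -0.126 in 6419c5 and 0.806 in 6694c2, both past the threshold), Id3 (0.32) and Tgfbr1 (0.30, centred 0.11 with adjusted p = 0.0889). Of 28 hypoxia and glycolysis genes, 8 rose and 4 fell (8 and 5 adjusted over the list alone, 3 and 2 centred), with Adm at 0.39, Pfkp at -0.32, Pdk1 at -0.29 and Egln3 at 0.21. The centred p of Adm and Pfkp was 0.0601 and 0.182. Of 23 genes for H3K9 methylation enzymes and readers, 10 rose and 7 fell, and with chromosomes centred 1 rose and 2 fell. The named members Kdm1a (0.29), Kdm4c (0.28), Kdm4b (0.25) and Suv39h1 (0.23) did not pass when centred (adjusted p = 0.0935, 0.246, 0.0607 and 0.794). Of 18 AP-1 and immediate early genes, 7 rose and 3 fell (7 and 4 adjusted over the list alone, 5 and 1 centred). Mafk (0.35), Ier3 (0.23) and Jun (0.23, centred 0.04) were higher, and Batf3 passed over the list alone (-0.37, adjusted p over all genes = 0.0599).

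Of 26 cell cycle genes, 4 rose and 4 fell (3 and 2 centred), with E2f2 at 0.35, Cdkn1a at 0.19 and the replication licensing genes Mcm6 and Mcm3 at -0.28 and -0.23. The latter pair lies on chromosome 1, and with chromosomes centred Mcm6, Mcm3 and Cdkn1a did not pass (adjusted p = 0.142, 0.653 and 0.214). Of 9 genes reported as Kdm3a targets in other tissues, 3 rose and 3 fell (1 and 3 centred): Ppargc1a, a coactivator of mitochondrial genes (0.69), was higher, and Adra1a (-1.09) and Acadvl (-0.31) were lower. Of 22 ribosomal and housekeeping genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone, 2 and 4 centred), with Hprt at 0.38 and Rps3 at -0.26. The centred p of Hprt was 0.101. Markers of other cell types were little covered. None of 3 fibroblast genes (Col3a1 -0.06, Rgs5 0.02), none of 5 leukocyte genes (Cd4 0.27, Spi1 -0.17) and neither of the endothelial genes measured (Sox17 -0.25, Pecam1 -0.26) passed, and 2 of 3 acinar and islet genes fell (Cela1 -0.57, Prss2 -0.54, centred adjusted p = 0.0704 and 0.0836).

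Among the gene families, 19 of 21 protocadherin genes on chromosome 18 rose in H3K9ac (21 adjusted over the list alone, 12 centred), but these share 6 regions and hold 5 distinct values. Pcdhga7, Pcdhgb4, Pcdhga8 and Pcdhgb5 were all at 0.30. Of 8 olfactory receptor genes 1 fell (Olfr986, -0.52, from 0.383 in 6419c5 and -1.42 in 6694c2), of 18 Hox genes 2 rose and 4 fell (0 and 0 adjusted over the list alone, and none centred), and of 309 Zfp genes 53 rose and 59 fell (50 and 53 adjusted over the list alone, 19 and 33 centred, with Zfp354a at -1.19, Zfp334 at -1.09, Zfp2 at -0.98 and Zfp229 at -0.83). The 2 vomeronasal genes measured were at -0.08 and -0.02. camera with the preset correlation called only the protocadherin list (adjusted p = 1.07e-13), and its adjusted p = 0.582 with an estimated correlation. The other 18 lists had adjusted p of 0.182 to 0.984. With chromosomes centred the mesenchymal and antigen presentation lists passed too (adjusted p = 0.0303 and 0.0401 with the preset correlation, 0.644 and 0.644 with an estimated correlation). fry, which asks whether the members of a list move 1 way on balance and does not compare them with other genes, passed for 10 of 19 lists, and for 16 when members may move either way, with a smallest adjusted p of 0.0595 for 1 direction after centring. For the cell cycle, Kdm3a target, ribosomal, fibroblast, leukocyte and Zfp lists the median, mean and camera direction differed in sign.

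Within 6419c5, more epithelial genes lost H3K9ac than gained it, and more mesenchymal genes gained it than lost it. Of the 24 epithelial genes 12 fell and 3 rose, with Foxa1 at -1.83 (adjusted p = 7.19e-08) and Elf3 at -1.01 (adjusted p = 2.15e-07), and of the 16 mesenchymal genes 8 rose and 1 fell, with Twist1 at 1.80 (adjusted p = 4.09e-05) and Prrx1 at 1.17 (adjusted p = 5.23e-05). The single regions that rose furthest lay in Igf2bp1, an RNA-binding protein gene (chromosome 11, 96004836 to 96006738), from 6.49 to 37.3 CPM (2.36), in the gap junction gene Gjc1 (1.88) and in Lhfp (1.75), and those that fell furthest in Lyplal1 (-2.38), Cnnm1 (-2.24) and Arhgef16 (-2.13). Of 34937 regions, 3411 passed in 6419c5 (1422 higher, 1989 lower) and 1764 with chromosomes centred. The fit on the 6419c5 libraries alone called 7639. The count was 1534 and 1459 without the wild-type replicates 1 and 2, 1583 and 1475 without the knockout replicates, and 6049 and 6050 without the 6694c2 knockout replicates. camera called the epithelial list lower (adjusted p = 0.000391) and the mesenchymal list higher (adjusted p = 0.000766), and neither kept its call with an estimated correlation (adjusted p = 0.438 for both).

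In 6694c2 H3K9ac was removed almost entirely from several regions that were strong in wild type. The region in Sall1, a zinc-finger gene (chromosome 8, 89041405 to 89043561), fell from 75.4 to 3.13 CPM (-4.29 ± 0.26 SE, adjusted p = 5.86e-11), that in Nectin1 (chromosome 9, 43743196 to 43745043) from 64.6 to 2.53 CPM (-4.29), and that in Prdm11 from 27.8 to 0.680 CPM (-4.12). The largest gains were 70622 bp from Ptpru (5.87 to 41.6 CPM, 2.63), in Ildr2 (5.60 to 30.0 CPM, 2.23) and in Arhgef10l (2.05). KDM3A reads of the 1 Mb around the Ptpru region were themselves higher by 0.715. Among the 12 epithelial genes that fell in 6419c5, Foxa1 was at 0.19 (adjusted p = 0.164) and Elf3 at 0.00 (adjusted p = 0.976) in 6694c2. These do not stand for all 12. In 6694c2, 7 of 24 epithelial genes rose and 3 fell, and 2 of 16 mesenchymal genes rose and 5 fell, Snai2 by -1.53 and Twist1 by -0.63. Of 34937 regions 7240 passed (3239 higher, 4001 lower), and 3039 with chromosomes centred. Centring gave 1445 higher and 1594 lower (47.55% higher). Correcting for the local level of KDM3A reads gave 3249 higher and 2659 lower, 55.0% higher against 44.7% in the main fit. KDM3A reads and H3K9ac did not shift equally in this line (-0.665 against -0.378 on chromosome 14, -0.117 against -0.222 on chromosome 2). The correction can therefore overshoot or undershoot, and nothing is concluded from its balance of gains and losses. The count without wild-type replicate 2 was 4691.

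The effect of the knockout on H3K9ac differed between the lines at 6361 regions (3289 with a higher value in 6419c5 and 3072 with a lower one). The widest differences, 6419c5 minus 6694c2, were at Prdm11 (4.24), Tln2, which encodes a focal adhesion protein (4.13, 0.62 against -3.51), and Sall1 (4.09) on 1 side and at Ildr2 (-3.46, -1.23 against 2.23), Ptpru (-2.84) and Arhgef16 (-2.58, -2.13 against 0.44) on the other. Foxa1 (adjusted p = 3.5e-07), Elf3 (adjusted p = 3.18e-06), Twist1 (adjusted p = 3.99e-05) and Snai2 (adjusted p = 0.000122) also differed between the lines. With chromosomes centred 2634 regions passed, and without single 6419c5 libraries 4086, 4019, 4187 and 3994 (wild-type replicates 1 and 2, knockout replicates 1 and 2). In wild type, 16309 H3K9ac regions differed between 6419c5 and 6694c2 (9016 higher and 7293 lower in 6419c5), and 4059 by at least 2-fold. With chromosomes centred 12304 regions differed. Egfr had 127 CPM in 6419c5 against 54.7 CPM in 6694c2, and Klf5 151 against 279 CPM. On chromosome 14, which holds Klf5, the median wild-type difference of 6419c5 from 6694c2 was itself -0.485 for H3K9ac and -1.03 for KDM3A reads.

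**Figure D3:**
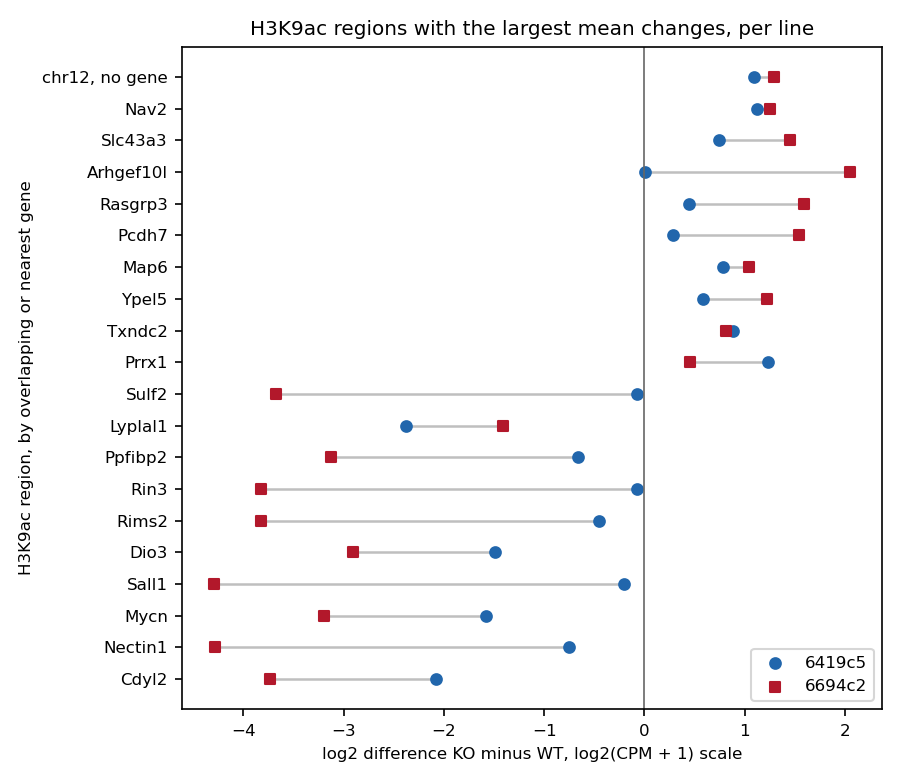
Log2 difference of H3K9ac between knockout and wild type at the 20 named regions with the largest mean changes. Each region has 1 point per line, and its points are joined. The Cdyl2 region fell in both lines (19.9 to 3.91 and 33.1 to 1.70 CPM) and the Nav2 region rose in both (30.5 to 67.5 and 21.0 to 51.5 CPM).

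The largest changes of H3K9me2 were smaller than those of H3K9ac. The mark fell furthest over both lines in Ttll11, a tubulin-modifying enzyme gene (chromosome 2, 35859814 to 35865509), from 14.5 to 8.89 CPM in 6419c5 and from 16.4 to 5.99 CPM in 6694c2 (-0.98 ± 0.09 SE, adjusted p = 1.61e-10). This region lies in a run of 19 neighbouring regions that lost the mark in 6694c2 (35572458 to 35901891, mean -0.84). KDM3A reads over that run were lower by -0.479 in 6694c2 (SE 0.144). The mark rose furthest in a region of chromosome 4 with no gene within 100 kb (92255145 to 92260915, 1.003 ± 0.09 SE, adjusted p = 6.9e-11). It lies in a run of 84 neighbouring regions that gained the mark in 6694c2 (90062073 to 92769447, mean 1.01), over which KDM3A reads in that line were higher by 0.714 (SE 0.332). Of the 10 named gains, 6 the 10 named gains lay between 60332270 and 61039713 of chromosome 17, also without a gene nearby (0.82 to 0.94, past the threshold in both lines). KDM3A reads around those 6 regions were higher by 0.466 to 0.518 in 6419c5 and by 0.189 to 0.272 in 6694c2. Of 86177 regions 14233 passed (8112 higher, 6121 lower), 1 of them at least 2-fold. With chromosomes centred 4593 passed, of which 3742 were among the 14233.

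The remaining named gains were at 4:131608343 (0.89), near Ptpru (0.86) and at 4:92272760 (0.84), and the remaining losses were in Robo1 (-0.82), St8sia6 (-0.76) and Slco3a1 (-0.69), near Ranbp6 (-0.73), Sfmbt2 (-0.73), Slc9a4 (-0.71) and Rrm2b (-0.68), and at 16:73156592 (-0.78) and 16:73461573 (-0.71). All 20 passed with chromosomes centred, and 13 passed in both lines. Correction for local KDM3A reads left 5536 calls. Leaving out single libraries gave 7880, 7644 and 7385 calls without 6419c5 wild-type replicates 1 and 2 and knockout replicate 2, and 7366 without 6694c2 wild-type replicate 1.

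By gene, 2099 of 9579 passed for H3K9me2 (788 higher, 1311 lower), and 305 with chromosomes centred. None of 19 EGF receptor signalling genes passed (Hbegf 0.22, Sos1 0.21) and none of 12 antigen presentation genes (B2m -0.17). Of 16 KLF and TGF-beta/SMAD genes 2 rose (Bambi 0.38 among them) and 3 fell (Klf7 -0.26 and Klf6 -0.20 among them). Of 21 chemokine and cytokine genes 1 rose (Ccl5 0.21) and 3 fell (Il1b -0.30, Il33 -0.25, Ccl20 -0.19, the last at 0.05 when centred). Of 15 epithelial genes 2 rose and 1 fell: Krt7, a ductal keratin gene (0.42, from 1.11 in 6419c5 and -0.268 in 6694c2), Gata6 (0.19) and Ehf (-0.12, 0.03 when centred). Of 14 mesenchymal genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with Lox at 0.52, Tnc at 0.30, Twist2 at -0.26 and Prrx1 at -0.22, the last at 0.02 when centred. Among 16 hypoxia genes 1 fell over all genes and 0 when adjusted over the list alone (Eno1 0.30, P4ha2 0.26 as values, limma, 3346 of all genes under an unadjusted p of 0.05). Of 12 H3K9 enzyme and reader genes 1 rose (Ehmt2 0.42) and 1 fell (Cdyl -0.25), of 8 AP-1 genes 2 fell (Egr3 -0.33, Fos -0.21, with Jun at 0.23 also past over the list alone), and of 9 cell cycle genes 1 rose (Ccnd3 0.33) and 1 fell (Mcm3 -0.27).

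Of 9 genes reported as Kdm3a targets in other tissues, 1 rose in H3K9me2 (Ppargc1a 0.35) and 2 fell (Adra1a -0.49, Tnp1 -0.47), and Ucp1 (0.34) also passed over the list alone (2 and 2). Ppargc1a gained both marks in the 6694c2 knockout (H3K9me2 0.65, adjusted p = 8.02e-09, and H3K9ac 1.19, adjusted p = 1.48e-08). Of 7 fibroblast genes 2 rose (Dcn 0.40, Col1a2 0.37) and 1 fell (Rgs5 -0.31), of 5 leukocyte genes 1 fell (Ptprc -0.18, 0.06 when centred), of 7 endothelial genes 1 rose (Tek 0.50) and 2 fell (Sox17 -0.28, Pecam1 -0.28), and of 10 acinar and islet genes 2 fell (Ins2 -0.37, Neurod1 -0.23). In the H3K9me2 lists described so far, only Krt7, Il33, Ccl5, Adra1a, Ppargc1a and Pecam1 passed with chromosomes centred. Of 34 protocadherin genes 31 rose (32 adjusted over the list alone, none centred), from 8 regions with 4 distinct values on chromosome 18 (Pcdha1 to Pcdha4 0.37 each, centred 0.19 with adjusted p = 0.437). Of 186 olfactory receptor genes 31 rose and 23 fell (36 and 31 adjusted over the list alone, 15 higher and none lower when centred, Olfr1335 0.48, Olfr314 0.46, Olfr341 -0.44, Olfr1330 0.43), of 38 vomeronasal receptor genes 8 fell (none when centred, Vmn1r212 -0.44, Vmn1r216 -0.42, Vmn2r79 -0.40, Vmn1r211 -0.39), and of 155 Zfp genes 12 rose and 11 fell (12 and 10 adjusted over the list alone, 2 higher and none lower when centred, Zfp474 0.62, Zfp35 0.46, Zfp804b 0.46, Zfp219 -0.36). The only member of the ribosomal and housekeeping list measured, the housekeeping gene Ywhaz, was at 0.01, and Hox genes carried no tested H3K9me2 region. camera called only the protocadherin list (adjusted p = 5.62e-15, and adjusted p = 1 with an estimated correlation), the other 18 lists lay at 0.177 to 1, and with chromosomes centred the olfactory receptor list passed as well (adjusted p = 1.42e-05 with the preset correlation, 0.94 with an estimated correlation). The smallest adjusted p of fry for 1 direction was 0.0988, and 17 of 19 lists passed for either direction. The mesenchymal, H3K9 enzyme, cell cycle, leukocyte, endothelial and Zfp lists differed in sign between median, mean and camera direction.

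Within 6419c5, H3K9me2 over the epithelial keratin gene Krt7 rose (chromosome 15, 101427511 to 101431002, 1.12 to 4.53 CPM, 1.39 ± 0.15 SE, adjusted p = 1.33e-08), and regions in and beyond the high-coordinate end of Robo1, which encodes a SLIT receptor, lost the mark. At 16:73086191, 38700 bp from Robo1, it fell from 31.2 to 10.8 CPM (-1.45, adjusted p = 2.38e-11), and at 16:73156592 and 16:73428351 by -1.28 and -1.27. Intergenic regions at 17:77405604 and 17:77432955 rose by 1.21 and 1.15, with KDM3A reads around them higher by 0.509 and 0.513. In all, 6458 regions passed (2777 higher, 3681 lower), and 1998 with chromosomes centred. The fit on this line alone called 12121, and the count was 2004, 1707, 3548 and 1364 without wild-type replicates 1 and 2 and knockout replicates 1 and 2, and 11034 and 11005 without the 6694c2 knockout replicates. In 6694c2 the mark fell in Scara3 (chromosome 14, 65926931 to 65935155, 27.1 to 7.88 CPM, -1.67), near Samd4 (-1.38) and in Ttll11 (-1.35), and rose at 4:92255145 (1.49) and near Izumo3 (1.42, 4:92112534), both in the run of chromosome 4 described above, and at 4:131608343 (1.38). The 1 Mb around Scara3 and Samd4 was lower in KDM3A reads by -0.623 and -0.787, and that around 4:131608343 higher by 0.679. KDM3A reads over the run that holds the Ttll11 region were lower by -0.479. Of the tested regions 19578 passed (11231 higher, 8347 lower), 6811 with chromosomes centred, and 8784 and 11153 without wild-type replicate 1 or 2.

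The knockout effect on H3K9me2 differed between the lines at 12082 regions (4889 higher and 7193 lower in 6419c5), most widely at Krt7 (1.77), Scara3 (1.69) and the fatty acid receptor gene Ffar4 (1.51, 0.66 against -0.85), and near Nuak1 (-1.71, -0.76 against 0.96), at 10:124277594 (-1.63) and at 10:124014471 (-1.62). The regions near Nuak1 and at 10:124277594 and 10:124014471 lie on chromosome 10. Its median difference between the lines in the knockout effect was itself -0.395 for H3K9me2 and -0.522 for KDM3A reads. With chromosomes centred 3694 passed. The count was 6549, 5663, 7798 and 5962 without 6419c5 wild-type replicates 1 and 2 and knockout replicates 1 and 2, and 6380 and 7108 without 6694c2 wild-type replicates 1 and 2. In wild type 45376 regions differed between the lines (21588 higher and 23788 lower in 6419c5), 27897 with chromosomes centred.

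**Figure D4:**
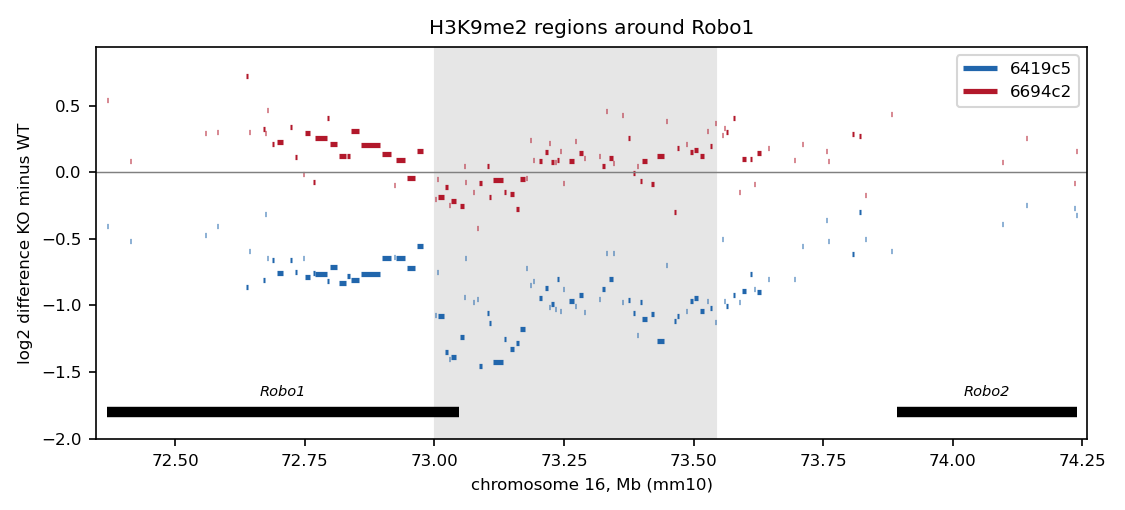
Log2 difference of H3K9me2 between knockout and wild type at regions along chromosome 16 around the end of Robo1, by position in Mb and line, with the named interval shaded. In 6419c5 the 65 regions from 73000879 to 73543039 fell by -0.554 to -1.45, and in 6694c2 they averaged 0.04.

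KDM3A reads showed no region that differed between knockout and wild type. limma called 0 of 221548 regions for the mean of both lines (9649 at an unadjusted p under 0.05, where 11077 are expected by chance), 0 in 6419c5 (12388), 0 in 6694c2 (8301) and 0 for the difference between the lines (9616), with smallest adjusted p of 0.994, 0.831, 1 and 0.991. edgeR on 9 libraries also called 0 in each. The regions of smallest p were at 1:77262216 (-1.81), in Sdk1 (1.99), 81430 bp from Hmga2 (2.31), at X:47224243 (1.81) and near 1700003H04Rik (1.51). With a median of 3 to 9 reads per region, simulated 4-fold changes were called in 12% of cases. That simulation changed few of its 221512 regions, so most isolated differences of that size were not detectable at this depth. A fall of many regions together was not simulated. In wild type 1 region differed between the lines, named here after its value was seen: X:45519038 to 45519450, with no gene within 100 kb, had 31 reads over the 6419c5 wild-type libraries and 0 over those of 6694c2 (adjusted p = 0.00159). The knockout libraries had 31 and 18 reads there, so the region was not without reads in 6694c2. It did not pass with chromosomes centred (count 0), and the count was 0 without 6419c5 wild-type replicate 1 or 2, 30 without 6694c2 wild-type replicate 1 and 16 without replicate 2. edgeR also called 1 region.

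Summed by gene, 36 of 16833 genes passed for KDM3A over both lines (19 higher, 17 lower), and 0 with chromosomes centred (limma, 1333 at an unadjusted p under 0.05 before centring). In 6419c5 65 passed, in 6694c2 51, and 30 differed between the lines. No member of the 16 lists or 5 families passed over all genes (limma, the same 1333). Adjusted over the list alone, 1 of 21 hypoxia genes was lower (Hk2, a hexokinase gene, -0.58, adjusted p over all genes = 0.194), 2 of 20 mesenchymal genes passed (Zeb1 0.36, Prrx1 -0.62) and 8 of 56 protocadherin genes were higher (Pcdhga12 0.42, Pcdhga11 0.36, Pcdha1 and Pcdha2 0.30). The named values of the remaining lists, none of which passed, were Erbb2 0.97 and Spry2 -0.79, Smad5 -0.725 and Smad6 -0.53, Cxcl1 0.735 and Cxcl2 0.60, Isg15 -0.94 and Erap1 -0.69, Foxa1 -1.04 and Hnf4a 0.66, Setdb2 -0.75 and Uhrf1 0.51, Fosl2 0.91 and Jund 0.41, Cdk2 1.16 and E2f3 -0.75, Acadm 0.38 and Ucp1 0.35, Rps18 0.74, Pdgfra 0.86 and Pdpn 0.46, Itgax -0.86 and Cd3d -0.59, Pecam1 -0.42 and Sox17 -0.38, Cela2a 1.06 and Gcg 0.50, Olfr916 and Olfr917 1.32, Hoxb5 -0.87 and Hoxd4 -0.83, Zfp592 1.56 and Zfp316 1.48, and Vmn2r61 -1.23 and Vmn1r197 -1.06. camera called the protocadherin list (adjusted p = 1.46e-16, and adjusted p = 0.41 with an estimated correlation), and the other 20 lists lay at 0.647 to 0.959. The smallest adjusted p of fry was 0.301, and the KLF, mesenchymal, fibroblast and Hox lists differed in sign between median, mean and camera direction.

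Of the KDM3A regions 1.53% overlapped H3K9ac regions and 22.8% overlapped H3K9me2 regions. The share of KDM3A reads that fell in them was close to this, 1.44% to 1.79% per library for H3K9ac and 22.8% to 24.6% for H3K9me2. Knockout and wild type differed by 0.0555 percentage points for H3K9ac (exact permutation p = 0.117, 120 arrangements, smallest possible 0.017) and by -0.0179 for H3K9me2 (exact permutation p = 0.917). Because no KDM3A region was lower past the threshold, the 1000 regions of smallest p among those lower in the knockout were compared with other regions. They need not have lost KDM3A, since 9649 regions lay under an unadjusted limma p of 0.05 where 11077 are expected by chance. The comparison therefore could not show whether the histone marks follow KDM3A. The 13 H3K9ac regions overlapping them differed from other regions by 0.01 (exact permutation p = 0.944, 36 arrangements, smallest possible 0.056), and the 230 H3K9me2 regions by -0.05 (exact permutation p = 0.0556, camera p = 0.0159 with an estimated correlation). With chromosomes centred the H3K9me2 difference was -0.02 (exact permutation p = 0.111, camera p = 0.292 with an estimated correlation).

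The knockout effects of the 2 lines were almost uncorrelated over regions, which are not independent replicates. For H3K9ac r was -0.00538 (rho -0.0329), and all 36 arrangements of the genotype labels within lines gave an absolute r as large. For H3K9me2 r was 0.0604 (rho 0.0448), and 12 of 36 arrangements gave one as large. Fold changes from separate replicate pairs of the same line correlated at 0.554 in 6419c5 and 0.442 in 6694c2 for H3K9ac and at 0.518 and 0.537 for H3K9me2, and with chromosomes centred at 0.52 and 0.376 and at 0.383 and 0.342. H3K9ac passed as higher in both lines at 292 regions, lower in both at 296 and in opposite directions at 534, where independent lists would give 132, 228 and 347, and H3K9me2 at 852, 346 and 558, against 362, 357 and 749. With chromosomes centred the H3K9ac counts were 76, 164 and 218, against 29.9, 47.5 and 76, and the H3K9me2 counts 136, 76 and 114, against 43.2, 32.6 and 82.1, so that all 3 kinds of overlap lay above the number for independent lists in both marks.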

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

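The tests for copy number, replicate spread and read depth below were chosen after the results were seen, and the test for KDM3A signal that does not depend on the gene was planned before. Results are given here because the knockout effect differed between the lines past the threshold of the interaction test.

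Chromosomes, or long parts of them, shifted between knockout and wild type in H3K9ac, H3K9me2 and KDM3A reads alike. If the copy number of chromosomes or of their parts differed, all 3 antibodies would shift together, and the lowest of 4 correlations over chromosomes between a histone mark and KDM3A reads was 0.877. Chromosome number alone does not describe the shifts, because KDM3A reads stepped by at least 0.3 within 3 chromosomes of 6419c5, and both histone marks stepped the same way on all 3. Over 5 Mb windows, each less the median of its chromosome, the 4 correlations were 0.203 to 0.576. Spread between these replicate libraries, which may be technical, does not account for it. Of 32 combinations of chromosome, mark and line with a shift above 0.1, replicate libraries ranged as widely in 1. Whether separate cultures of 1 genotype would range more widely cannot be told from them. A difference in copy number between the knockout and wild-type cells may therefore lie behind these shifts, and DNA was not measured directly because inputs were not used here. Whether the knockout, the selection of clones or later culture brought it about was not tested.

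The knockout effects of the lines did not correlate over regions. Noise between replicates would also lower the correlation within a line, but the lowest r of a histone mark from separate replicate pairs of a line was 0.442 as deposited and 0.342 with chromosomes centred, and the highest r between the lines as deposited was 0.0604. Copy number might hide a common effect, but the highest between-line r after centring each chromosome was 0.0294, and after centring in 5 Mb windows, which also removes steps within chromosomes, 0.0157. The data leave open whether the lines respond differently to loss of Kdm3a or whether each knockout carries changes of its own, since the labels do not say how many clones were used.

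No KDM3A region differed between knockout and wild type. Depth could account for this, since 12% of simulated 4-fold changes were called where few regions changed. A fall of many regions together was not simulated. Signal that does not depend on the gene could too: at the 1000 regions highest in 1 wild-type library, the other libraries differed between knockout and wild type by a mean log2 of -0.0123 in 6419c5 and 0.085 in 6694c2. Loss of the protein would have lowered both values if the regions held KDM3A, and both explanations remain possible. Splits of the genotype labels gave 0 regions throughout: real count 0 and highest other 0 for the mean of both lines, for the difference between the lines and for 6419c5 alone. A count of 0 is the lowest that any split can give, so these splits decide nothing.

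Of the other counts, the splits within the histone marks are too few for a share under 0.05. The real count for H3K9ac over both lines was 5644 and the highest other 6361 (2 of 18 splits as large), and that for the difference between the lines 6361 and 5644 (1 of 18). For H3K9me2 they were 14233 and 12082 (1 of 18), and 12082 and 14233 (2 of 18). By gene they were 5609 and 6353 for H3K9ac (2 of 18) and 2099 and 1640 for H3K9me2 (1 of 18). In each of these cases the highest other count was that of the split with the genotypes swapped in 1 line. Such a split turns the mean of both lines into the difference between them, or the reverse. It keeps knockout and wild type apart within each line, so its count does not show what random labels would give. For gene lists, 1 list was called against a highest other of 4 for H3K9ac (14 of 18) and of 5 for H3K9me2 (15 of 18). For KDM3A lists 27 of 60 splits were as large (highest other 2), so chance cannot be excluded. For KDM3A genes the real count of 36 was above the highest other of 30 (1 of 60). That 30 equals the count for the difference between the lines, and 0 genes were left after centring chromosomes. Splits of replicates that may be technical cannot part the knockout from shifts of chromosomes, so nothing is concluded from this count.

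H3K9ac regions differed between the lines in their knockout effect at 6361 regions and H3K9me2 at 12082. The values that follow are the knockout effect in 6419c5 minus that in 6694c2, on the log2 scale. For H3K9ac regions they were 4.24 (Prdm11), 4.13 (Tln2), 4.09 (Sall1), 3.75 (Rin3), 3.6 (Sulf2), 3.53 (Nectin1), 3.37 (Rims2), 3.14 (Igf2bp1), 2.56 (Lhfp), 2.46 (Ppfibp2), 2.27 (Gjc1), 1.65 (Cdyl2), 1.62 (Mycn), 1.41 (Dio3) and 0.776 (Prrx1). In the other direction they were -3.46 (Ildr2), -2.84 (Ptpru), -2.58 (Arhgef16), -2.17 (Cnnm1), -2.05 (Arhgef10l), -1.26 (Pcdh7), -1.14 (Rasgrp3), -0.967 (Lyplal1) and -0.639 (Ypel5).

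For H3K9me2 regions the differences were 1.77 (Krt7), 1.69 (Scara3), 1.51 (Ffar4), 1.48 (Samd4), 1.31 (Rrm2b), 0.988 and 0.677 (Ttll11, 2:35888299 and 2:35859814), 0.804 and 0.771 (17:77405604 and 17:77432955), 0.799 (Sfmbt2), 0.604 (St8sia6) and 0.552 (Ranbp6). In the other direction they were -1.71 (Nuak1), -1.63 and -1.62 (10:124277594 and 10:124014471), -1.39 (16:73428351), -1.37 and -1.16 (Robo1, 16:73086191 and 16:73027510), -1.23 (Izumo3), -1.01 (4:92272760), -1.01 (16:73156592), -0.992 (4:131608343), -0.966 (4:92255145), -0.814 (16:73461573) and -0.680 (Ptpru).

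H3K9ac summed over genes differed by 2.85 (Zfp334), 2.43 (Twist1), 1.81 (Zfp229), 1.80 (Olfr986), 1.76 (Snai2), 1.58 (Zfp2), 1.31 (Egfr), 1.23 (Cela1), 1.0 (Zfp354a), 0.823 (Prrx1), 0.732 (Acadvl), 0.681 (Fn1), 0.617 (Spry2), 0.573 (Pdk1), 0.533 (Klf5), 0.457 (Egln3), 0.415 (Kdm3a), 0.326 (Kdm4b), 0.275 (Smad4), 0.259 (Erbb2) and 0.240 (Pcdhga7, Pcdhgb4, Pcdhga8 and Pcdhgb5). In the other direction it differed by -2.02 (Foxa1), -1.01 (Elf3), -0.999 (Ppargc1a), -0.932 (Klf4), -0.613 (Kdm4c), -0.556 (Cxcl3), -0.461 (Cx3cl1), -0.447 (Cxcl16), -0.432 (Mcm6), -0.431 (Rps3), -0.399 (Mcm3), -0.362 (Hprt), -0.346 (Kdm1a), -0.334 (Suv39h1), -0.306 (Cdkn1a), -0.305 (E2f2) and -0.269 (Jun).

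H3K9me2 summed over genes differed by 1.38 (Krt7), 0.682 (Cdyl), 0.536 (Il33), 0.526 (Zfp219), 0.475 (Klf6), 0.423 (Adra1a), 0.386 (Egr3) and 0.279 (Gata6), and by -0.851 (Tek), -0.683 (Jun), -0.602 (Ppargc1a), -0.549 (Tnc), -0.462 (Ptprc), -0.453 (Ins2) and -0.344 (Vmn1r211) in the other direction.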

How the results depend on the processing

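Direction was kept by every named region under every alternative. These regions were picked from the same data for large changes or small p, so this was largely set by the choice. Results of named genes were less stable. Over all alternatives 1393 stayed on the same side of the threshold, 212 no longer passed, 12 newly passed and 19 turned direction. Alternatives marked in the methods as added were chosen after seeing the data. With chromosomes centred the H3K9ac counts were 2563 (mean of both lines), 1764 (6419c5), 3039 (6694c2) and 2634 (difference between the lines), and the H3K9me2 counts 4593, 1998, 6811, 3694 and 27897 (lines in wild type). Correction for local KDM3A reads gave 2023 H3K9ac regions in 6419c5, and 5536, 2244, 11408 and 6957 H3K9me2 regions (mean, 6419c5, 6694c2, difference). Centring removes the median shift of a chromosome. The correction subtracts the local level of KDM3A reads, which did not shift by the same amount as the histone marks. In 6694c2 chromosome 14 lay at -0.665 for KDM3A reads, against -0.378 for H3K9ac and -0.397 for H3K9me2. Chromosome 2 lay at -0.117, against -0.222 and -0.234. The correction can therefore overshoot or undershoot and leave shifts of chromosomes or their parts. The fit on 6419c5 alone gave 7639 H3K9ac and 12121 H3K9me2 regions. It takes its spread from that line only, while the main fit shares 1 spread over all groups. The 6694c2 knockout replicates, the furthest apart by chi-square, enter that shared spread. Whether this is the whole cause was not tested, and the counts of the lines do not compare the size of their effects. A mean of at least 5 CPM, which tests fewer regions, gave 28176 H3K9me2 regions between the wild-type lines. KDM3A gave 1 region in 6694c2 with a pseudocount of 0.1 CPM, and between the wild-type lines 3 with a mean of at least 5 CPM and 0 with chromosomes centred. Called lists fell to 0 for each antibody with an estimated correlation and to 0 with regions within 2 kb of either gene end, and with chromosomes centred were 3 for H3K9ac and 2 for H3K9me2.

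Leaving out 1 library at a time, where the lone library is assumed to vary like the other groups, gave 3538 to 7939 H3K9ac regions (mean), 1459 to 6050 (6419c5), 4691 to 9197 (6694c2) and 3994 to 9046 (difference). The mean count was 3602, 3538, 3673 and 3632 without 6419c5 wild-type replicates 1 and 2 and knockout replicates 1 and 2, the 6419c5 count 1534, 1459, 1583 and 1475, and the difference 4086, 4019, 4187 and 3994. The 6419c5 count was 6049 and 6050 without 6694c2 knockout replicates 1 and 2, and the 6694c2 count 4691 without wild-type replicate 2. H3K9me2 ranged over 7366 to 20587, 1364 to 11034, 8784 to 23674 and 5663 to 18051. In the same library order the mean was 7880, 7644 and, without knockout replicate 2, 7385, the 6419c5 count 2004, 1707, 3548 and 1364, and the difference 6549, 5663, 7798 and 5962. Without 6694c2 wild-type replicate 1 they were 7366 (mean), 8784 (6694c2) and 6380 (difference), without replicate 2 11153 (6694c2) and 7108 (difference), and the 6419c5 count was 11034 and 11005 without the 6694c2 knockout replicates. KDM3A between wild-type lines ranged over 0 to 30 (0 without 6419c5 wild-type replicate 1 or 2, 30 and 16 without 6694c2 wild-type replicates 1 and 2), in 6694c2 over 0 to 2 (1 without wild-type replicate 1, 2 without knockout replicate 1) and for the difference over 0 to 1 (1 without 6694c2 wild-type replicate 1). Lists ranged over 1 to 2 (2 for H3K9ac without 6694c2 knockout replicate 2, and 2 for H3K9me2 without 6419c5 knockout replicate 1, 6694c2 wild-type replicate 2 or 6694c2 knockout replicate 1). The r between lines for H3K9me2 was 0.0294 with chromosomes centred, 0.0157 with 5 Mb windows centred and 0.0386 to 0.0745 with 1 library left out (0.0459 without 6419c5 wild-type replicate 1, 0.0386 and 0.0745 without 6694c2 wild-type replicates 1 and 2, 0.0440 without 6694c2 knockout replicate 2).

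Values that turned direction were H3K9ac Prrx1 -0.0199 (gene ends) and Smad4 -0.0193 (centred), H3K9me2 centred Klf5 0.0313, Smad4 -0.0740, Ccl20 0.0493, Ehf 0.0284, Prrx1 0.0206 and Ptprc 0.0620, and Kdm3a -0.000233 without 6419c5 knockout replicate 1 (highest 0.0828, without knockout replicate 2). For KDM3A they were Kdm3a -0.106, Egfr 0.423 and Pcdhga11 -0.151 (gene ends), Smad4 -0.126 (centred), Kdm3a -0.00289 and Smad4 -0.0124 without 6419c5 wild-type replicate 3, Kdm3a -0.0140 and Smad4 -0.0117 without knockout replicate 2, and Kdm3a -0.0163 and -0.0489 without 6694c2 wild-type or knockout replicate 1 (highest values 0.0671 for Kdm3a and 0.0828 for Smad4). H3K9me2 at KDM3A regions was 0.0495 where a KDM3A region had to cover at least 0.5 of the H3K9me2 region, from 1 region. The cause was not tested.

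The labels do not say that libraries of 1 replicate number share a culture or day, so the numbers were not treated as pairs. Same-numbered libraries correlated at -0.000948 and -0.0722 (H3K9ac, 6419c5 and 6694c2), 0.0643 and 0.0171 (H3K9me2), -0.00733 to 0.00539 and 0.0132 (KDM3A). With 2 pairs the r of other-numbered libraries is the same value with the sign turned (0.0643 and -0.0643, for example), so those values cannot show whether the numbers pair the samples. With 3 pairs, 1 of 3 wild-type KDM3A libraries of 6419c5 matched its own number best. A replicate block gave 5207, 3116, 6768, 5929 and 13204 H3K9ac regions, 16404, 7904, 21561, 14162 and 39966 H3K9me2 regions, 0 KDM3A regions, the wild-type line difference included, and 1 list for each antibody.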

Other observations

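The tests of runs of regions and of an epithelial to mesenchymal shift were chosen after the results were seen, and that of opposite changes of the marks was planned before.

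In 6419c5 knockout cells H3K9me2 was lost over a stretch of 542 kb that begins in Robo1 and runs beyond its high-coordinate end (chromosome 16, 73000879 to 73543039). All 65 neighbouring regions of this run fell, by -0.554 to -1.45 (mean -1.0, largest adjusted p = 0.0477), while in 6694c2 they averaged 0.04 with 0 past the threshold (limma, line contrasts). A run was defined as neighbouring regions called the same way in a line, so that all 65 passed in 6419c5 was fixed by the choice. How often chance would give such runs was not tested. KDM3A reads over the stretch differed by -0.0725 (SE 0.0718) in 6419c5, which leaves -0.932 beyond that level. Over Robo1 as a whole H3K9me2 was lower by -0.80 in 6419c5 (adjusted p = 1.23e-06) and H3K9ac over Robo1 by -1.925 (adjusted p = 1.1e-05, difference between the lines adjusted p = 0.000836). On either side, beyond 1 region that did not pass, lay shorter runs that also fell in 6419c5 (72695331 to 72976977, 21 regions, mean -0.722, and 73558327 to 73711453, 12 regions, mean -0.855), so the loss reached further than this stretch. In 6694c2 these averaged 0.151 and 0.156, with 4 and 1 regions past the threshold. The stretch was the longest of 35 such runs in 6419c5, with 186 in 6694c2, and 23 of the 68 runs with enough KDM3A regions to give a local level exceeded that level by at least 0.5.

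At Krt7, a keratin gene of ductal epithelium, the marks moved in opposite directions and did so differently in each line. In 6419c5 H3K9me2 over Krt7 rose by 1.11 (adjusted p = 4.41e-07) and H3K9ac fell by -0.94 (adjusted p = 7.7e-07), and in 6694c2 H3K9me2 fell by -0.27 (adjusted p = 0.0467) and H3K9ac rose by 0.61 (adjusted p = 1.48e-05). The difference between the lines had adjusted p = 4.97e-07 for H3K9me2 and 1.35e-07 for H3K9ac.

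Across genes with both marks, which are not independent replicates, such opposite changes were not the rule. If H3K9me2 rose where H3K9ac fell, their changes would correlate negatively, but r over 6859 genes was 0.397 in 6419c5 and 0.370 in 6694c2, with chromosomes centred 0.193 and 0.112, and with 5 Mb windows centred 0.134 and 0.0853 (6782 genes). The hypothesis that loss of Kdm3a moves the marks in opposite directions was therefore not borne out over genes as a whole. Of the genes past the threshold in both marks, 374 in 6419c5 and 937 in 6694c2 moved the same way, where independent changes would give 103 and 440. These counts include the shifts of chromosomes, and with chromosomes centred they were 50 and 72 against 10 and 31.2. Opposite changes were also found more often than that in 1 direction per line when centred: H3K9ac lower with H3K9me2 higher at 12 genes in 6419c5 (4.61 expected) and 8 in 6694c2 (17 expected), and H3K9ac higher with H3K9me2 lower at 0 (5.3 expected) and 23 (13.2 expected).

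A second hypothesis was that H3K9ac shifts from epithelial to mesenchymal genes in the 6419c5 knockout. The higher of the camera p values of the lists, with an estimated correlation and chromosomes centred, was 0.0868 (mesenchymal) and the other 0.0244 (epithelial). These cannot tell whether the lists as such moved, although Foxa1 and Twist1 changed by -1.83 and 1.80 in that line.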
